A study of Homo sapiens with 4 samples.

How the data were processed

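Total RNA of Huh7.5 cells, taken 72 h after transfection with 100 nM control or miR-185 mimic, was isolated with a Qiagen RNeasy kit and labelled with an Affymetrix whole-transcript kit, per the labels' protocols. The labels give 2 control and 2 miR-185 arrays as biological replicates and do not say which strand of miR-185 the mimic supplies. The deposited values are log2 signals per probe set. Per the submitters' processing notes the tools were Affymetrix Expression Console, RMA and Transcriptome Analysis Console, with versions not given in the sources used here. The base of the logarithm is not stated. Base 2 was taken from the use of RMA and from the range of the values, which ran from 0.48 to 14.3, and every fold change rests on it. The array medians lay between 5.01 and 5.04, and no pair of arrays held identical values. Arrays give no read depth, so their number limits the precision.

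Gene names came from a table of the platform's annotation. Of 53617 probe sets, 16098 named 1 gene, 0 named several and 37519 were unnamed here. The named ones covered 14884 genes, and for the 779 genes with more than 1 probe set the one with the highest mean was used. The genome build was not given in the sources used here, so no coordinates are reported. The level filter was meant to be set from olfactory receptor genes, which liver cells do not express. Since 1 such gene was named and 50 were required, the fallback fixed with it was used, a mean above the median of named genes (log2 6.12), which left 7442 genes.

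Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, all 4 arrays), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The fit had 2 residual and 3.31 prior degrees of freedom. Each p-value therefore leans on the spread shared across genes. Gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 26 of 32 lists with 5 or more tested genes. An estimated correlation was tried beside it, under which 0 lists passed (smallest adjusted p = 0.945), as was fry, under which 1 list passed. The 6 lists with fewer tested genes were bile acid synthesis (0), antigen presentation (4), xenobiotic metabolism (2), mitochondrially encoded transcripts (0), histone genes (0) and markers of other cell types (3). Of the 26 lists tested, 1 that camera did not pass is not reported here, though it stayed in the adjustment. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

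The design, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the 12 highest and 12 lowest genes by log2 difference among those past the adjusted threshold whose groups did not overlap, all tested members of the reported miR-185 targets, up to 4 members with the smallest p in each list described, and MIR185 with TANGO2 whatever their values. Fewer than 12 genes were higher, so all 5 are named. In some lists fewer than 4 members are named. The reported targets came from general knowledge of the literature, and no target resource was used.

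On simulated data with 7442 genes, 200 of them changed, and 20 simulations, limma called 4.48% of genes changed by 0.5 log2 units, 80.2% of those changed by 1 and 97.8% of those changed by 2, and 4.97% of its calls were false. Camera passed 20 of 20 shifted lists of 15 genes and 2 of 20 unshifted ones at an unadjusted p under 0.05. The simulated genes varied independently and with the same spread in both groups. In the data the sterol list had an estimated correlation of 0.738, and the miR-185 arrays differed more than the controls. The simulated rates therefore need not hold for these arrays.

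The alternatives tried were no level filter, trended and robust variance, a further quantile normalization, centring on array medians, the mean of a gene's probe sets, the replicate number as a block, array weights, other thresholds and each array left out in turn. Filters at the lower and upper quartile were added after seeing the data. The planned stricter filter was identical to the one used. A planned test of miR-185 seed sites in 3' UTRs was not run, because no UTR sequences were used here.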

Results

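Huh7.5 is an established human hepatoma line, derived from Huh7 and widely used because it is permissive for hepatitis C virus. The cells were transfected with 100 nM of a control mimic or of a miR-185 mimic, a synthetic RNA that supplies the microRNA, and total RNA was taken 72 h later. Expression was measured on 4 whole-transcript microarrays, 2 per group, which the labels call biological replicates. The comparison asked which transcripts differed after delivery of miR-185, a microRNA studied in liver cells for its repression of lipid genes. The median log2 signal over all 53617 probe sets was 5.01 and 5.04 on the control arrays and 5.01 on both miR-185 arrays. The control arrays differed from each other by a median of 0.076 log2 units per tested gene, and the miR-185 arrays by 0.173. No gene differed by 1 log2 unit or more between the control arrays, while 74 genes did between the miR-185 arrays. The number of arrays limits the precision of every value. All differences below are miR-185 mimic minus control mimic on the log2 scale, with n = 2 per group.

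RANBP3L, a Ran-binding protein reported to export Smad proteins from the nucleus, rose most. Its level on probe set 16995301 went from 4.73 ± 0.027 to 8.74 ± 0.058 (SD, n = 2), a 16.2-fold rise with a limma adjusted p of 0.00048. The control level lay under the 6.12 that a gene's mean had to exceed to be tested, and no measure of background was used here. The other 4 genes that rose were PBLD (2.61-fold, SE 0.097 log2), the pseudogene GGT3P (2.40-fold, SE 0.096), PODN (2.34-fold, SE 0.10) and TJP3 (2.30-fold, SE 0.11). PODN encodes podocan, a small leucine-rich proteoglycan of the extracellular matrix, and TJP3 the tight junction protein ZO-3. Their limma adjusted p-values ran from 0.036 for PBLD to 0.048 for TJP3.

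Among the 12 genes that fell, ANXA13, an annexin that binds membrane phospholipids, fell furthest. Its level on probe set 17080814 went from 7.58 ± 0.020 to 5.61 ± 0.13 (SD, n = 2), or 0.256 of the control level, with a limma adjusted p of 0.021. The miR-185 means of ANXA13 and of TTC5, at 5.61 and 5.82, lay under the filter level of 6.12, with no background measured, so their ratios and ranks are less certain. DKK1, a secreted inhibitor of Wnt signalling, fell to 0.332 of its control level and FST, the activin-binding protein follistatin, to 0.387. MBOAT4, the acyltransferase that octanoylates ghrelin, fell to 0.368 and CYFIP1, a subunit of the WAVE regulatory complex, to 0.387. The remaining genes were the tyrosine kinase FRK (0.418), CRYBG1 (0.441), the protein O-mannose kinase POMK (0.455), the transcription factor KLF7 (0.473), TTC5 (0.481), the protease inhibitor TFPI2 (0.523) and the pseudogene NSFP1 (0.525). The limma standard errors of these 12 differences lay between 0.091 for NSFP1 and 0.16 for DKK1, and the adjusted p-values between 0.021 for ANXA13 and 0.0495 for DKK1, TFPI2 and NSFP1. On both miR-185 arrays each of the 17 genes lay on the same side of both control arrays. NSF, the parent gene of NSFP1, differed by −0.96 (SE 0.097, adjusted p = 0.052), so NSFP1 is uncertain as a gene of its own. The other probe sets of GGT3P differed by 1.10 and 0.60, and it too is uncertain because its family shares sequence.

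**Figure D1:**
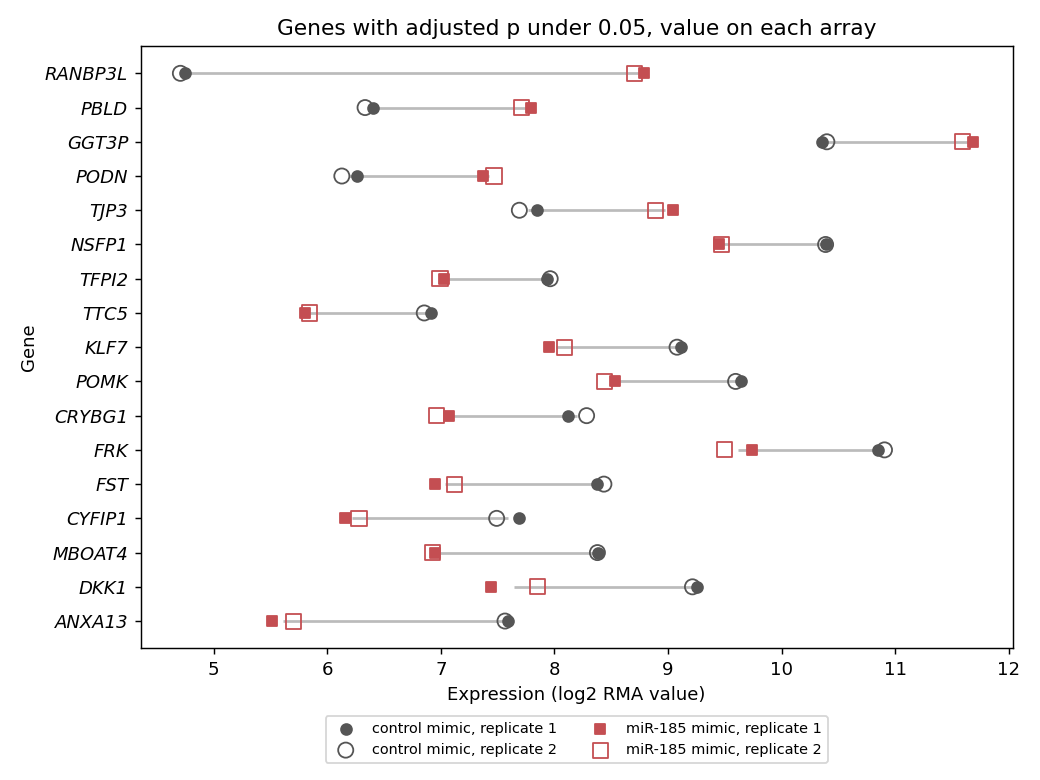
The 17 genes with a limma adjusted p under 0.05, with the log2 level on the horizontal axis 1 point per array (circles, 2 control mimic; squares, 2 miR-185 mimic) and grey lines joining the group means. RANBP3L stands apart, at 4.73 in control cells and 8.74 after the miR-185 mimic, and ANXA13 shows the lowest ratio, 0.256.

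These 17 genes, 5 higher and 12 lower, were the ones past an adjusted p of 0.05 among 7442 tested. At an unadjusted p under 0.05 there were 896 higher and 650 lower genes, 20.8% of those tested against 5% by chance. Without control replicate 2 there were 529, of which 42.0% were higher, against 58.0% with all arrays, and without control replicate 1 there were 586. The groups did not overlap for 54.7% of genes, where chance gives 33.3%, so an exact permutation test of single genes cannot reach 0.05 with these arrays. Only RANBP3L passed when no level filter was applied. With 1 array left out, 1 group had no spread of its own, so counts from such fits rest on the other group's spread alone.

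The reported targets of miR-185, a list assembled from general knowledge of the literature, held 11 tested genes of 20. KLF7 alone passed over all genes, falling by 1.08 (SE 0.10). Adjusted over the list alone, 1 gene was higher and 3 were lower. SREBF2, the transcription factor that drives sterol synthesis genes, differed by −1.09 (SE 0.20, adjusted p = 0.088 over all genes), 0.471 of its control level. It lay at −1.38 on miR-185 replicate 1 and −0.79 on replicate 2. HMGA2, a chromatin protein, differed by −0.60 (adjusted p = 0.103). SCAP, the escort protein of the SREBP factors, lay on the opposite side at 0.61 (SE 0.093, adjusted p = 0.077). The differences of the others were −0.33 for SREBF1 (−0.51 and −0.15 on the separate miR-185 arrays), −0.20 for HMGA1 (−0.34 and −0.051), −0.15 for the DNA methyltransferase DNMT1 (−0.052 and −0.26), 0.05 for RHOA, 0.13 for STIM1, 0.15 for VEGFA (0.057 and 0.24) and 0.29 for AKT1, with adjusted p-values from 0.227 to 0.796. The other probe set of HMGA1 differed by 0.04 and that of AKT1 by 0.15. RHOA and STIM1 changed sign when miR-185 replicate 2 was left out. The list as a whole had a mean of −0.20, or −0.12 without miR-185 replicate 1, and did not pass (camera adjusted p = 0.405). The probe set of MIR185, the gene that encodes miR-185, differed by 0.21 (0.12 and 0.29 on the separate miR-185 arrays, adjusted p = 0.391) and its host gene TANGO2 by −0.13 (adjusted p = 0.489). Whether the MIR185 probe set reads the transfected mimic was not tested, so its value does not measure delivery.

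The sterol list, fixed as genes of cholesterol synthesis and uptake, held among its tested members synthesis enzymes, the regulator INSIG1 and the sterol transporter STARD4, and no uptake gene. It fell by camera at the preset correlation, with a mean of −0.58, an SD over genes of 0.34 and 0.668 of the control level (15 tested genes of 26, adjusted p = 8.7e-05). The estimated correlation between its genes was 0.738, against the preset 0.01, and with it the call was lost (camera unadjusted p = 0.278, adjusted p = 0.945). That adjusted p was the same for all 26 lists tested, so it does not tell them apart. The estimated correlation rests on 2 residual degrees of freedom and takes in the split between the miR-185 arrays given below. Over the lists it ran from −0.13 to 0.90. Nor did fry pass the sterol list (adjusted p = 0.657). Of these genes 14 were lower and 1 was higher, and for 13 both miR-185 arrays lay below both controls. No member passed singly, either over all genes or adjusted over the list alone, and 6 had an unadjusted limma p under 0.05. The 4 members with the smallest p were HMGCS1, the cytosolic HMG-CoA synthase, at −0.86 (adjusted p = 0.105), ACAT2 at −0.78, NSDHL at −0.76 and the mevalonate kinase MVK at −0.76. On miR-185 replicate 2 the last 3 lay at −0.50, −0.47 and −0.43. TM7SF2, a sterol reductase named after its values were seen, was the higher one at 0.18. Its sign turned without miR-185 replicate 2. The miR-185 arrays stood apart from each other here. The list's mean against the controls was −0.94 on replicate 1 and −0.23 on replicate 2. Without either, the miR-185 group had no spread of its own, so a camera test there would rest on the controls alone.

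Fatty acid and triglyceride synthesis genes had 12 lower and 5 higher members of 17, with a mean of −0.21 (camera adjusted p = 0.058). None passed over all genes. Adjusted over the list alone, FASN, the fatty acid synthase (−0.74), ACACA, which makes malonyl-CoA (−0.51), and the elongase ELOVL6 (−0.59) were lower, and DGAT1, which catalyses the last step of triglyceride synthesis, was higher at 0.51. Here too the arrays stood apart, with a list mean of −0.42 on miR-185 replicate 1 and −0.0066 on replicate 2. With 1 array left out the mean ran from −0.42 to −0.0066, and 1 group then had no spread of its own to test with. Targets of the liver X receptors had a mean of −0.37 over 6 genes (camera adjusted p = 0.105). It moved to −0.57 without miR-185 replicate 2 and to −0.18 without replicate 1. LPCAT3, an acyltransferase that puts polyunsaturated chains into phospholipids, differed by −1.39 (SE 0.26, adjusted p = 0.088) and was the 1 member that passed adjusted over the list alone. MYLIP, the ligase that degrades the LDL receptor, differed by −0.33, from control levels of 7.69 and 7.45 that lay apart. Regulators of the SREBP pathway had a mean of −0.14 and a median of 0.05 over 8 genes (camera adjusted p = 0.908), their means being −0.31 and 0.03 on the separate miR-185 arrays. SCAP and SREBF2 passed adjusted over that list alone, in opposite directions, while ERLIN2, which takes part in the degradation of HMG-CoA reductase, differed by 0.27 and INSIG1 by −0.92 (SE 0.40), at −1.56 on miR-185 replicate 1 and −0.29 on replicate 2.

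**Figure D2:**
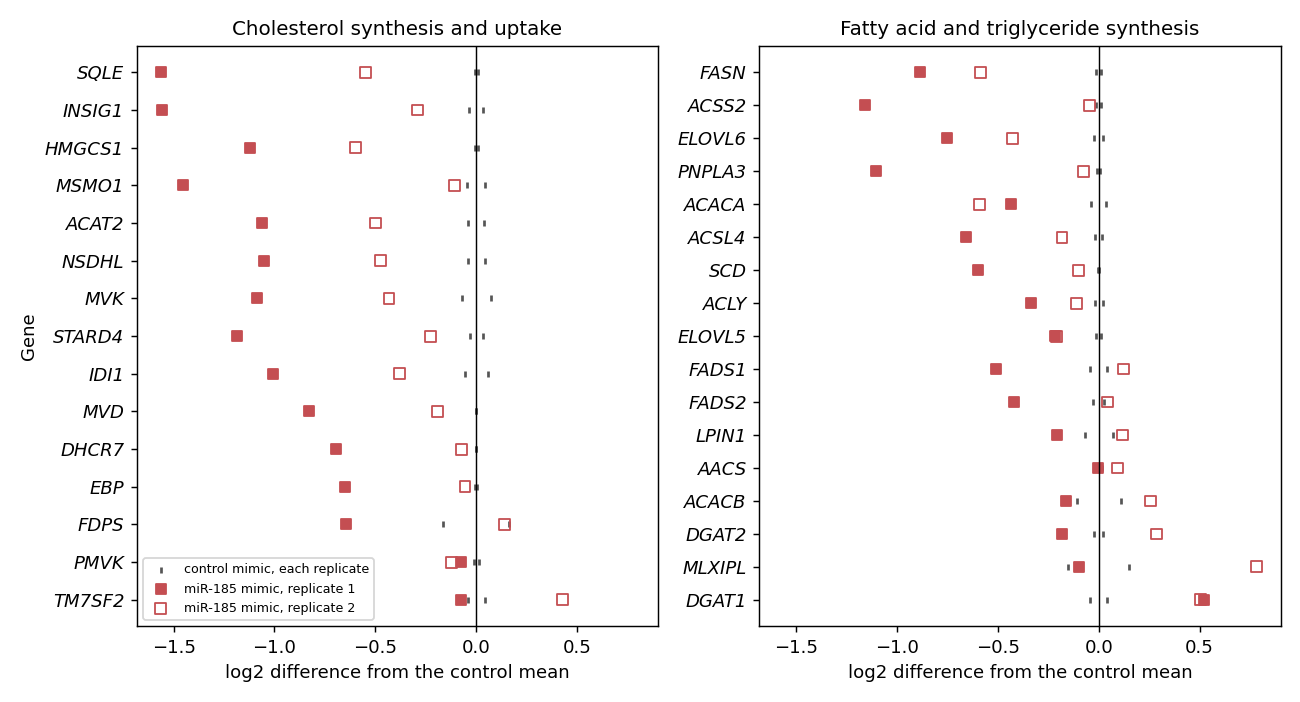
Genes of the sterol list and of the fatty acid and triglyceride list, with the log2 difference from the control mean on the horizontal axis, a square per miR-185 array and a tick per control array. The sterol genes averaged −0.94 on replicate 1 and −0.23 on replicate 2, with TM7SF2 the 1 gene whose mean was higher, and its sign depended on the array.

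No list of liver functions other than the sterol list passed. Lipoprotein assembly and secretion had a mean of 0.10 over 12 genes, 7 higher and 5 lower (camera adjusted p = 0.703). APOM, the apolipoprotein that carries sphingosine-1-phosphate, differed by 0.83 (SE 0.11, adjusted p = 0.073), with its other probe sets at 0.86, and LCAT, the plasma cholesterol acyltransferase, by 0.47. Both passed adjusted over the list alone. APOC3, an inhibitor of triglyceride clearance, differed by −0.50 (SE 0.41), at −1.15 on miR-185 replicate 1 and 0.15 on replicate 2. Fatty acid oxidation and ketogenesis had a mean of 0.11 over 8 genes, 5 higher and 3 lower (camera adjusted p = 0.597). Its 4 members that passed adjusted over the list alone were all higher: the peroxisomal thiolase ACAA1 at 0.77 (adjusted p = 0.087 over all genes), CPT2 at 0.45, HADH at 0.39 and ACSL1 at 0.33. CPT1A, which brings fatty acids into mitochondria and is named after its value was seen, lay lower at −0.68 (SE 0.38), with −1.27 and −0.095 on the separate miR-185 arrays. Hepatocyte identity genes had a mean of 0.087 over 20 genes, 12 higher and 8 lower (camera adjusted p = 0.883). PROX1, a transcription factor of hepatocytes, differed by −0.61 (SE 0.098, adjusted p = 0.081) and was the 1 member past the threshold adjusted over the list alone. HPX, which binds haem in plasma, differed by 0.48. Complement and acute phase genes had a mean of 0.21 over 11 genes, 8 higher and 3 lower (camera adjusted p = 0.703), with none past the threshold adjusted over the list alone. Haptoglobin, HP, differed by 0.71 (adjusted p = 0.109) and coagulation factor F10 by 0.47, from control levels of 6.95 and 6.63. KNG1 differed by −0.45 (−0.62 and −0.28 on the separate miR-185 arrays), with its other probe set at −0.094. C3 differed by −0.43 (−0.69 and −0.18). In each of these 4 lists the mean was below 0 on miR-185 replicate 1 and above 0 on replicate 2, from −0.11 to 0.53 for the complement list.

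Cell cycle genes were mixed. Mitosis genes had a mean of −0.073 over 27 genes, 19 of them lower (camera adjusted p = 0.109), with none past the threshold adjusted over the list alone. The mean moved to −0.10 without miR-185 replicate 2 and to −0.044 without replicate 1. The proliferation marker MKI67 differed by −0.44 and BIRC5, which encodes survivin, by 0.31. DNA replication genes had a mean of −0.030 over 25 genes (camera adjusted p = 0.721), from −0.011 without control replicate 1 to −0.050 without control replicate 2. The cyclin E genes lay on opposite sides: CCNE1 was at 0.507 of its control level (−0.98, SE 0.13, adjusted p = 0.073) and CCNE2 at 1.84 times its level (0.88, SE 0.14, adjusted p = 0.081). GINS1, a subunit of the replicative helicase, differed by −0.84 (adjusted p = 0.075) and GINS3, of the same complex, by 0.28. CCNE1, GINS1 and CCNE2 were the 3 genes that passed adjusted over the list alone.

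Of 11 tested host factors of hepatitis C virus, 10 were higher, and the list's mean was 0.11, or 0.073 without miR-185 replicate 1 (camera adjusted p = 0.405). FASN was the lower one. The median difference over all genes tested was also above 0, at 0.031. FASN and DGAT1 passed adjusted over the list alone. EPHA2, an entry factor of the virus, differed by 0.39 and the oxysterol-binding protein OSBP by 0.24. Interferon-stimulated genes had a mean of −0.15 and a median of 0.13 over 8 genes (camera adjusted p = 0.746), and their mean was −0.065 without the level filter. CXCL10, a chemokine, differed by −1.20 (SE 0.16, adjusted p = 0.073) and HERC5, the ligase that attaches ISG15, by −0.80 (adjusted p = 0.098). Both passed adjusted over the list alone, with miR-185 means of 5.79 and 6.04 that lay under the filter level. USP18, which removes ISG15, differed by 0.38 and MX2 by −0.20 (−0.28 and −0.13 on the separate miR-185 arrays). NF-kB and inflammation genes had a mean of 0.17 over 6 genes (camera adjusted p = 0.703), which was 0.082 without control replicate 1, 0.26 without control replicate 2 and 0.0050 without the level filter. The adhesion molecule ICAM1, at 0.63 (adjusted p = 0.096), and the chemokine CCL20, at −0.34, passed adjusted over the list alone. NFKB2 differed by 0.51, from control levels of 6.52 and 6.91 that lay apart, and NFKB1 by 0.29.

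Lysosome and autophagy genes had a mean of 0.19 over 14 genes, 0.19 on each miR-185 array. Both miR-185 values lay above both control values for 10 of them, as they did for 2389 of all 7442 genes tested. The list missed the threshold by camera (adjusted p = 0.058, and 0.945 with an estimated correlation) and passed by fry, which does not compare it with other genes (adjusted p = 0.011). Without the level filter camera passed it too (adjusted p = 0.016). The protease CTSB differed by 0.58 (SE 0.092, adjusted p = 0.081) from a control level of 6.07, under the filter level, the autophagy receptor SQSTM1 by 0.43 and the hexosaminidase subunit HEXA by 0.38, and these 3 passed adjusted over the list alone. ATG9A differed by 0.23.

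The p53 targets had a mean of 0.011 over 12 genes (camera adjusted p = 0.883), with a negative median (−0.010) and camera direction, and their mean turned to −0.018 under a further quantile normalization (adjusted p = 0.865). Camera sets a list against the other genes tested, and the median difference over all genes tested was 0.031. Adjusted over the list alone, 1 member passed on each side, the cytokine GDF15 at 0.45 and the phosphatase TIGAR at −0.51. Epithelial junction genes had a mean of −0.036 and a median of 0.026 over 10 genes (camera adjusted p = 0.862). TJP1, which encodes ZO-1, differed by −0.60 (SE 0.11, adjusted p = 0.088) and was the 1 member past the threshold adjusted over the list alone, whereas MARVELD2, which encodes tricellulin, differed by 0.33. None of the remaining 8 lists passed by camera or had a member past the threshold adjusted over the list alone. Their means, with camera adjusted p-values, were 0.094 for ribosomal proteins (0.342), 0.13 for the unfolded protein and integrated stress response (0.703), 0.13 for Wnt and Hippo targets (0.703), 0.036 for glycolysis and hypoxia (0.721) and 0.051 for oxidative stress genes of NRF2 (0.883). They were −0.052 for AKT and mTOR signalling (0.703), 0.080 for epithelial-mesenchymal transition, whose median was −0.027 (0.883), and 0.021 for the microRNA machinery, whose median was −0.046 and camera direction negative (0.883). The means of the p53, junction, glycolysis, NRF2, AKT, epithelial-mesenchymal and microRNA machinery lists had opposite signs on the separate miR-185 arrays. On replicates 1 and 2 the means were 0.018 and 0.24 for the stress response, 0.23 and 0.035 for Wnt and Hippo targets, and 0.033 and 0.15 for ribosomal proteins.

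**Figure D3:**
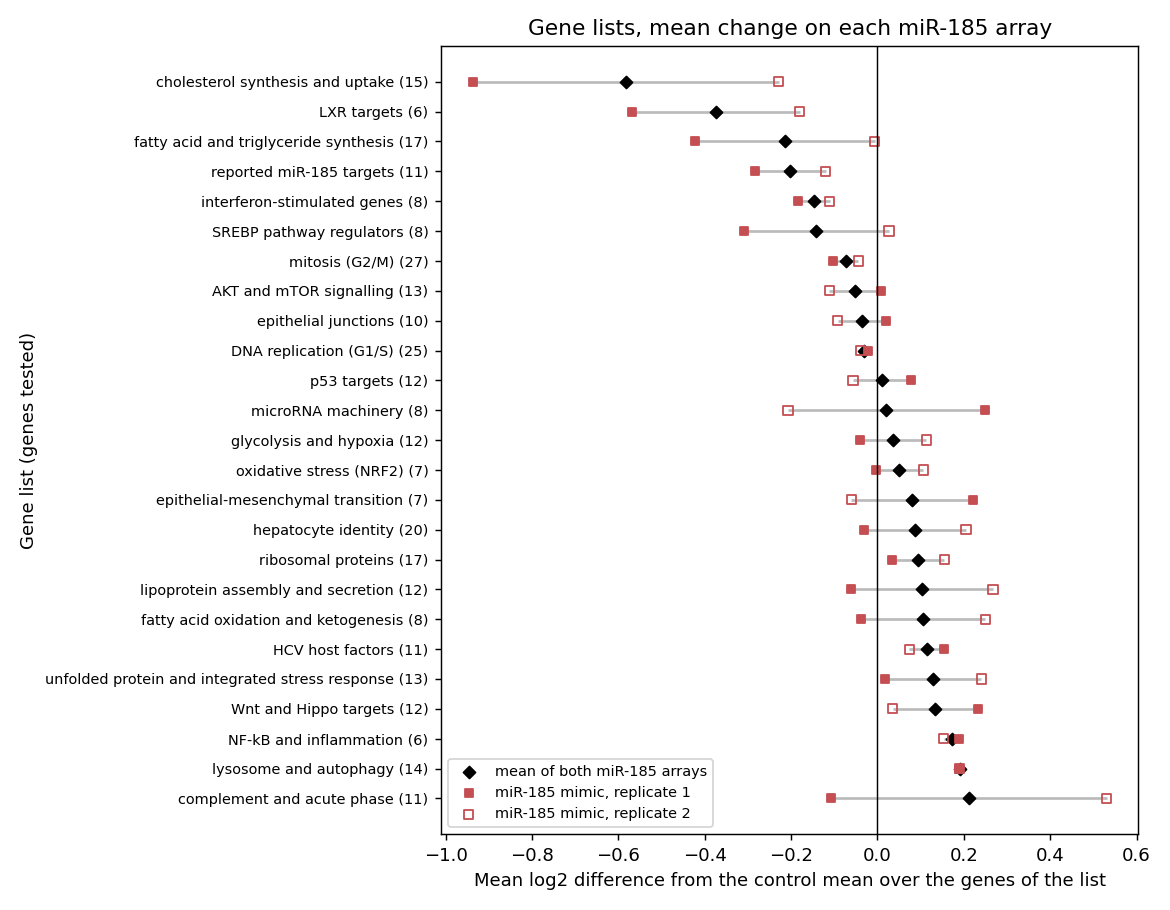
The 25 tested gene lists that are reported, with the mean log2 difference from the control mean on the horizontal axis, for each miR-185 array (squares, joined by a line) and for both together (diamonds). The sterol list lies lowest at −0.58 and was the 1 list called by camera at its preset correlation, a call lost with an estimated correlation (adjusted p = 0.945); the p53 list turned negative, to −0.018, under a further quantile normalization.

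Markers of other cell types could not be tested as a list, since 3 of 15 named genes passed the level filter. LYZ differed by 0.01 (SE 0.25), CD68 by 0.45 (0.27 and 0.63 on the separate miR-185 arrays, adjusted p = 0.223) and DES by 0.33 (adjusted p = 0.196). LYZ changed sign with the array left out, from −0.36 to 0.38.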

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

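The test of probe sets without a gene name was chosen after the main result was seen. Those probe sets entered none of the gene comparisons, and they differed between the groups more often than chance gives. Of 8508 above the level filter, 1159 (13.6%) had an unadjusted limma p under 0.05, where chance gives 5%, with 650 higher and 509 lower. The share among the named genes tested was larger, at 20.8%, so the excess is not particular to unnamed probe sets. After adjustment 0 passed at 0.05 or at 0.1, the smallest adjusted p being 0.164. The probe sets with the smallest p were 16781573 and 17078626 among the higher, at 1.20 and 1.22, and 16874082 and 16661508 among the lower, at −1.76 and −1.30.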

How the results depend on the processing

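The quartile filters were chosen after seeing the data, as were, for the gene lists, the probe set mean and array weights, and, for the number of lists passed and the lists other than the sterol list, the scalings. All 17 genes kept their sign under every setting that tested them (7 of them under the upper quartile filter). Most settings could not have turned it. Their groups did not overlap, so leaving out an array cannot turn a sign. The filters, variance settings, block and array weights leave a gene's difference unchanged in this design. The count of higher and lower genes, 5 and 12 as reported, was 1 and 0 without a filter (limma, 1865 genes at an unadjusted p under 0.05), 1 and 3 with the lower quartile, 3 and 11 with the upper, and 8 and 21 with a trended variance, robust or not. It was 16 and 35 with array weights, 145 and 145 at an adjusted p under 0.1, and 11 and 26 at a fold of 2 with an unadjusted p under 0.05. The labels do not say whether arrays of equal replicate number were handled together. The correlation of their deviations was 0.028, which cannot settle this. With the replicate block the count was 1 and 1. Leaving out 1 array gave 1 to 1053 higher and 0 to 893 lower genes (586 genes at an unadjusted p under 0.05 where 0 were lower): 1 and 0 without control replicate 1, 1 and 1 without control replicate 2, 957 and 893 without miR-185 replicate 1, and 1053 and 781 without miR-185 replicate 2, the lone array of a group being assumed to vary like the other group's, so that the last 2 rest on the spread of the controls alone. Without a filter more genes share the adjustment, and the spread shared across genes differed too. The SE of GGT3P was 0.096 with the filter and 0.116 in a fit of all named genes. The parts of these 2 were not separated, and for the other settings the cause was not tested. The number of lists passed, 1 as reported, was 2 without a filter, 3 and 2 with the lower and upper quartile, 2 after median centring, 2 with the block, 2 with array weights, 0 with an estimated correlation and 1 to 4 with 1 array left out. The sterol list kept its mean of −0.583 with an estimated correlation but not its call (camera adjusted p = 0.945). Under the other settings with all 4 arrays its camera adjusted p ran from 9.2e-07 to 0.00039. Its mean ran from −0.937 to −0.229 with 1 array left out. With all 4 arrays the fatty acid list passed under both quartile filters, median centring, the block and array weights. The lysosome list passed without a filter and with the lower quartile. With 1 array left out, 1 group had no spread of its own, so list calls from such fits are not given.

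Signs turned for 12 lists. With 1 array left out, their means ran from −0.31 to 0.027 for SREBP regulators, −0.062 to 0.27 for lipoprotein genes, −0.039 to 0.25 for fatty acid oxidation, −0.030 to 0.21 for hepatocyte identity, −0.11 to 0.53 for complement, −0.057 to 0.078 for p53 targets, −0.0040 to 0.11 for NRF2 genes, −0.042 to 0.11 for glycolysis, −0.060 to 0.22 for epithelial-mesenchymal transition, −0.092 to 0.021 for junctions, −0.11 to 0.0082 for AKT and mTOR, and −0.21 to 0.25 for microRNA machinery. The p53 mean was −0.018 after a further quantile normalization. That setting also moved the median difference over all tested genes, from 0.031 to 0.012, and signs were counted about 0. Among genes, APOC3 ran from −1.15 to 0.15, RHOA from −0.0048 to 0.11, STIM1 from −0.029 to 0.29, TM7SF2 from −0.074 to 0.43 and LYZ from −0.36 to 0.38 (−0.030 with the mean of its probe sets). Over the 96 genes named, 1303 alternative values were computed, of which 7 turned sign, 80 lost a call and 128 gained one. Under the filters, variance settings, block and array weights no sign could turn, so 7 is not a measure of robustness. The calls lost and gained include fits with 1 array left out, where 1 group had no spread of its own. The causes of the changes were not tested. Signal over background, which limits dim genes, was not measured here.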

Other observations

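Of all genes tested, 145 were higher and 145 lower at the looser limma adjusted p under 0.1, those of the report included. The following, not named there, were picked from them after their values were seen. ACY3, an aminoacylase, differed by 1.65 (SE 0.28, adjusted p = 0.087). CIDEB, a lipid droplet protein that takes part in the maturation of very low density lipoprotein, differed by 1.13 (SE 0.16, adjusted p = 0.074), and GSTA2, a glutathione transferase of liver, by 1.11 (SE 0.22, adjusted p = 0.096) from a control level of 6.04, under the filter level. On the lower side were MAP1B, a microtubule-associated protein, at −1.40 (SE 0.20, adjusted p = 0.074), TMEM109 at −1.31 and TCTN3, a protein of the ciliary transition zone, at −1.28. CES1, a carboxylesterase, was at −0.69, MGLL, the monoacylglycerol lipase, at −0.67 and ELOVL2, an elongase of polyunsaturated fatty acids, at −0.62. IGFBP3, which binds insulin-like growth factors, differed by −0.82. Each of these genes lay on the same side of both controls on both miR-185 arrays, and none passed an adjusted p of 0.05.

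The tests of the sterol pattern and of the pseudogenes were chosen after the results were seen. The one that left out list members was written before its own result, with a limit of 0.3 taken from the random lists already drawn. The sterol list lay at −0.94 on miR-185 replicate 1 and −0.23 on replicate 2, a difference of 0.71 with 14 of 15 genes higher on replicate 2, against −0.044 between the control arrays. A mimic effect weaker by the same factor on every gene of replicate 2 would shrink other changes alike. Over the 200 genes outside the list with the largest mean change the ratio of replicate 2 to replicate 1 was 1.04 (95% bootstrap interval 0.956 to 1.14), against 0.244 (0.109 to 0.349) for the sterol list. This argues against such a uniform loss, but not against a loss limited to some genes. The 200 genes were chosen on the mean of both arrays, and the interval treats genes as independent. On replicates 1 and 2 the reported targets SREBF2, KLF7 and HMGA2 lay at −1.38 and −0.79, −1.15 and −1.01, and −0.49 and −0.71. An intensity-dependent offset left by the authors' normalization would move random lists of like expression, and 0 of 10000 differed as much (range −0.31 to 0.30). Nor did 1 or 2 genes drive it, since the mean difference without the 2 largest was 0.617; a candidate explanation that stays open is a difference in the state of the cultures, and no biological explanation was tested.

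The split between the miR-185 arrays was not limited to sterol genes. Replicate 2 was higher than replicate 1 by 0.64 for complement and acute phase genes and by 0.42 for fatty acid and triglyceride genes, differences that 0 of 10000 random lists reached, by 0.33 for lipoprotein genes (1 random list) and by 0.24 for hepatocyte identity genes (3 random lists). MicroRNA machinery genes differed the other way, by −0.46, as low as 0 of 10000 random lists. These lists were picked out of 26 after their values were seen. The random lists were matched on expression alone. Genes of the 5 lists varied together, with estimated correlations from 0.186 for hepatocyte identity to 0.903 for microRNA machinery. The random lists therefore do not measure how rare such splits are.

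NSFP1 and its parent gene NSF differed by −0.93 and −0.96, the same within their errors. This is consistent with NSF transcript being read on the NSFP1 probe set. For GGT3P the nearest tested relative was GGTLC2 at 0.248 (0.15 and 0.35 on the separate miR-185 arrays), well below the 1.26 of GGT3P, but GGT1 was not analysed here, so signal from another family member and a change of GGT3P itself cannot be told apart.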
